A study of Homo sapiens with 9 samples.

How the data were processed

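Expression was measured in neural stem cells (NSCs) derived from H9, an established human embryonic stem cell line, with 1 Affymetrix Human Genome U133 A 2.0 array per sample. LRRK2 encodes a large kinase and GTPase, and the G2019S change in it is a known cause of inherited Parkinson's disease that raises kinase activity. LRRK2-IN-1 is a small-molecule inhibitor of LRRK2 that is also known to act on DCLK1 and ERK5. The 9 arrays fell into 3 groups of 3 by their titles: wildtype cells, LRRK2 mutant knock-in cells that were mock treated, and LRRK2 mutant cells given 3 µM LRRK2-IN-1 for 5 days. Per the labels, 6 samples carried the change on 1 allele and 3 carried none. Total RNA was extracted with TRIzol, purified on columns and amplified with the manufacturer's 3' kit, per the labels' protocols.

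The deposited values were probe set intensities that had been summarised with RMA, per the submitters' processing notes. The version and settings of RMA are not given in the sources used here. RMA usually ends on a log2 scale, but the deposited intensity values ran from 7.631 to 32944, with array medians between 149.1 and 153.7, so they were read as linear and log2 was taken first. The close medians show values already normalised between arrays, and no further normalisation was applied in the reported results. Such normalisation assumes that most genes do not change, so a shift of all genes together would be removed by it. Summaries of dim probe sets sit near a floor, which makes fold changes of dim genes too small.

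The table held 22277 probe sets. The 62 control probe sets were left out, which left 22215. Gene names came from the platform annotation: 19064 probe sets had 1 gene symbol, 1043 had several and 2108 had no listed symbol. Symbols were checked against the RefSeq gene table of GRCh38.p14 through Entrez identifiers, where 19052 matched, 12 did not, and 0 symbols changed. Each gene was represented by 1 probe set with exactly 1 symbol, avoiding cross-hybridising sets where possible and taking the highest mean over all 9 arrays, which gave 11963 genes. For 4309 genes there was more than 1 probe set. Among genes called changed that had several probe sets, another probe set passed in the opposite direction for 4 of 1147 genes in mutant against wildtype cells, 39 of 1847 in treated against mutant cells, and 29 of 1210 in treated against wildtype cells. LRRK2 had no probe set of its own in this table and was not analysed here. The level of LRRK2 would be no firm check of the labels in any case, since the knock-in alters the sequence and need not alter the amount of RNA.

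Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit on the 3 group means over all 9 arrays and eBayes. The residual degrees of freedom were 6 and the prior added 4.47. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the 11963 genes, with calls at an adjusted p below 0.05. Changes are log2 differences of group means with the standard error (SE) of that fit. The median SD of a gene within groups was 0.105 on the log2 scale. The 3 comparisons were mutant against wildtype, treated mutant against mutant, and treated mutant against wildtype, with a moderated F test over the 3 groups. Overall similarity was measured as the root mean squared log2 difference of group means after subtraction of its sampling variance, and as distances between single arrays with exact permutation tests. The 2 comparisons that share the mutant arrays were set beside 100 simulated data sets in which treated cells had the mutant means. Those that share the wildtype arrays were set beside 100 sets with no effect in any group. Arrays were drawn as independent, with no tie between replicates of the same number.

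Fixed before the data were examined were the groups, the main fit and its alternatives, the rule for naming genes and 29 gene lists with 904 members, of which 770 were measured. The lists covered neural stem and progenitor genes, neuronal differentiation, astrocytes, the oligodendrocyte lineage, neural crest and mesenchyme, pluripotency, endoderm and mesoderm, forebrain identity, midbrain and hindbrain identity, HOX genes, the nuclear envelope, mitosis, DNA replication, and p53 and senescence. Further lists were oxidative phosphorylation, lysosome and autophagy, the unfolded protein response, heat shock, oxidative stress (NRF2 targets), and WNT targets. They also covered ERK feedback genes, familial Parkinson's disease genes, cholesterol synthesis, glycolysis and hypoxia, the interferon response, ribosomal proteins, the proteasome, axons and synapses, and the extracellular matrix. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 29 lists, and again with an estimated correlation per list and with fry. Genes named are the 10 largest changes in each direction whose arrays did not overlap, up to 4 members per list with the largest changes among those called, and fixed genes: the measured familial Parkinson's disease genes, LMNA, LMNB1, LMNB2, SOX2, NES, PAX6, MKI67 and CDKN1A. A further 5 lists were chosen after the data were examined: actin and SRF target genes, YAP and TEAD target genes, dorsal neural tube genes, ventral neural tube genes and clustered histone genes. Their p-values were adjusted over these 5 lists alone.

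The steps were tested on simulated data with known changes. In mutant against wildtype cells, over 11963 genes, 56 of 67 genes changed 1.5-fold (83.6%), 66 of 67 changed 2-fold (98.5%) and 66 of 66 changed 4-fold were recovered, and 9 of 197 calls were false (4.57%). In treated against mutant cells 83.6% of genes changed 1.5-fold and 100% of those changed 2-fold were recovered, with 5 false calls among 194. For treated against wildtype cells recovery at 1.5-fold was 86.6%, and 22 of 404 calls were false. Far fewer genes were changed in this simulation than were called in the data. In a simulated test of the 29 lists, 1 list was shifted by 0.3 on the log2 scale in mutant cells. Camera called it, and also called 1 of the other lists. The number of arrays limits the precision, and the labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

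The labels number the replicates alike in each group. After group means were removed, mutant and treated arrays of the same number correlated across genes at 0.33, 0.25 and 0.40, each higher than with any other number, so the numbers were taken to pair those samples, from the data and not from a statement in the labels. With the number as a replicate block over all 9 arrays, 4674 genes changed between treated and mutant cells, against 4494 without it. The block on only the 6 mutant and treated arrays gave 5022. Wildtype and mutant arrays of the same number correlated at 0.16, 0.27 and -0.20, and wildtype and treated arrays at 0.04, 0.07 and -0.13, which did not pair them. Alternatives covered a repeated quantile normalisation, centring of each array, a filter on dim genes, other probe set rules, another variance model, array weights, the replicate block, fits on 6 arrays, a fold threshold and leaving out each array in turn.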

Results

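The 9 arrays compared NSCs that were wildtype, LRRK2 G2019S mutant and mock treated, or LRRK2 mutant and treated with the kinase inhibitor LRRK2-IN-1 at 3 µM for 5 days, with 3 arrays per group. The design asked how alike the expression profiles of these 3 groups were. Genotype and cell line could not be separated, since all mutant arrays came from knock-in cells and all wildtype arrays from the parental line, and no wildtype cells received the inhibitor. No mock treatment is labelled for the wildtype cells, so comparisons with wildtype may also differ in that handling. The ratio of 3' to 5' GAPDH signal, a measure of RNA integrity and labelling, was 0.903 on the log2 scale on mutant array 3 and 0.889 on treated array 3, against 1.23 to 1.38 on the other 7 arrays. The same ratio for ACTB averaged 1.9 (SD 0.14) on mutant, 2.15 (SD 0.07) on wildtype and 2.16 (SD 0.34) on treated arrays. Every mutant array lay below every wildtype array in it, as did treated array 3 (1.8).

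The groups separated clearly. The mean distance between arrays of the same group was 0.178 (wildtype), 0.203 (mutant) and 0.160 (treated) log2 units per gene, against 0.406 between mutant and wildtype arrays, 0.508 between treated and mutant arrays, and 0.380 between treated and wildtype arrays. Between-group distances exceeded within-group distances by 0.25, the largest value among all 280 ways to split the 9 arrays (exact permutation test, p = 0.0036, the smallest these splits can give). After correction for sampling noise the group means lay 0.3576 (mutant to wildtype), 0.4736 (treated to mutant) and 0.3392 (treated to wildtype) apart. Treated cells were thus 0.0185 closer to wildtype than mutant cells were. Relabelling the mutant and treated arrays gave a difference as large in 10 of 20 assignments (two-sided exact permutation test, p = 0.5, where the smallest possible is 0.1). Most assignments mix both groups, which lie 0.4736 apart, so the test cannot tell whether 0.0185 exceeds the spread between arrays. That test did not use the replicate numbers, and within each number the treated array lay closer to the wildtype mean than the mutant array (0.351 against 0.375, 0.364 against 0.398 and 0.381 against 0.404). These single-array distances are not corrected for noise, and mutant arrays also lay farther from each other (0.203) than treated arrays did (0.160). With dim genes left out the order of the corrected distances turned, with mutant cells 0.3413 and treated cells 0.3525 from wildtype. The limma F test called 4883 of 11963 genes (40.8%) different among the 3 groups.

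**Figure D1:**
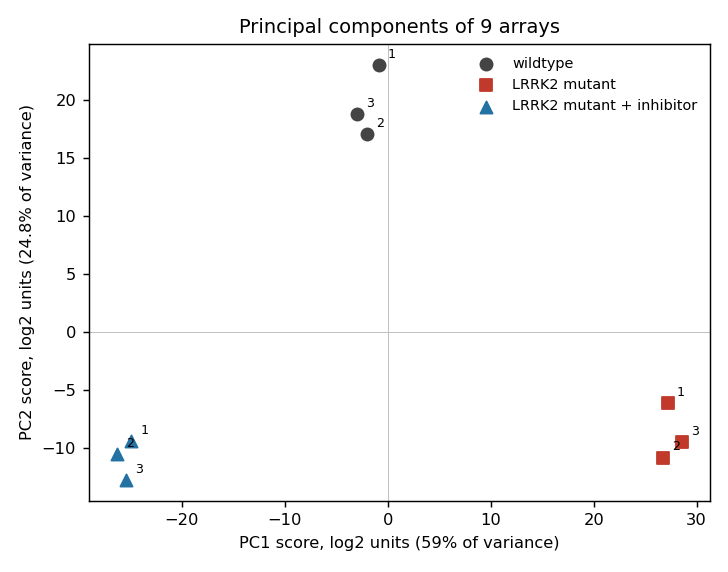
Scores of the 9 arrays on the first principal component (59% of variance, horizontal axis) and the next one (24.8%, vertical axis), in log2 units, with a symbol per array coloured by group and numbered by replicate. Mutant and treated arrays lie at opposite ends of the horizontal axis, with wildtype arrays between them and apart from both on the vertical axis.

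Among the largest single changes between LRRK2 mutant and wildtype NSCs were genes of neural patterning, extracellular matrix and growth factor binding. PAX6, a transcription factor of dorsal neural progenitors, was 16.5-fold lower (log2 change -4.04 ± 0.09 SE, n = 3 per group), and the ephrin receptor EPHA3 was 12-fold lower (-3.59 ± 0.11). IGFBP3, a secreted binder of insulin-like growth factors, was 19.3-fold higher (4.27 ± 0.08), and the ventral neural tube factors NKX2-2 and FOXA2 were 13.3-fold (3.74 ± 0.08) and 9.95-fold (3.31 ± 0.09) higher. The matrix protein SPP1 rose by 3.58 ± 0.11, the membrane protein EMP1 by 3.50 ± 0.10, the GABA receptor subunit GABRA5 by 3.42 ± 0.15 and the annexin ANXA3 by 3.41 ± 0.12. Also among the 10 largest increases were RGS1, a regulator of G protein signalling (3.29 ± 0.09), CRHBP, which binds corticotropin-releasing hormone (3.09 ± 0.19), and the selenium carrier SELENOP (3.07 ± 0.13). The other large decreases were in the neural crest factor TFAP2B (-3.07 ± 0.17), the dorsal spinal cord factor PRDM13 (-3.00 ± 0.11), and the collagen gene COL1A2 (-3.00 ± 0.07). They also included the WNT pathway genes FRZB (-2.88 ± 0.12), FZD10 (-2.84 ± 0.09) and LGR5 (-2.78 ± 0.15), the repressor RUNX1T1 (-2.54 ± 0.16) and the membrane skeleton gene ADD2 (-2.51 ± 0.12).

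In all, 2832 genes changed between mutant and wildtype cells (limma, adjusted p below 0.05), 1485 up and 1347 down. Of these, 330 changed at least 2-fold, 235 up and 95 down. The 3 arrays of each group did not overlap for 37.1% of all genes, where chance gives 10%.

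Genes of the cell surroundings rose as groups. Of 41 extracellular matrix genes, 23 rose, 7 fell and 11 did not pass (25 and 8 adjusted over the list alone; camera adjusted p = 1.33e-06, and adjusted p = 0.0551 with an estimated correlation). Beside SPP1, the neurotrophic serpin SERPINF1 rose by 3.03 ± 0.11, the basement membrane gene NID2 by 2.70 ± 0.07 and IGFBP5 by 1.95 ± 0.06. Markers of neural crest and mesenchyme, other cell types that such cultures can hold, moved with them: 14 of 24 rose, 3 fell and 7 did not pass (the same 14 and 3 adjusted over the list alone; adjusted p = 0.000526, and adjusted p = 0.237 with an estimated correlation). The proteoglycan LUM rose by 1.93 ± 0.09 and the calcium-binding S100A4 by 1.33 ± 0.09, while COL1A2 and TFAP2B fell. With dim genes left out the adjusted p of this list was 0.0769. Among 14 measured endoderm and mesoderm markers 5 rose, 0 fell and 9 did not pass (5 and 0 adjusted over the list alone; adjusted p = 0.0176, and adjusted p = 0.219 with an estimated correlation). They were FOXA2, which the floor plate also expresses, and FOXA1 (1.12 ± 0.08), both also on the ventral neural tube list. The others were the transport protein TTR (1.31 ± 0.08), the fetal serum protein AFP (0.98 ± 0.07) and 1 more. The list median was 0.008 against a mean of 0.508, so a few large changes carry the mean.

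The lists of neuronal differentiation genes and of neural stem and progenitor genes fell as groups. Of 32 neuronal differentiation genes, 15 fell, 4 rose and 13 did not pass (18 and 4 adjusted over the list alone; adjusted p = 1.33e-06, and adjusted p = 0.026 with an estimated correlation). The bHLH factor NHLH1 fell by 1.88 ± 0.14, the microtubule regulators STMN2 and STMN4 by 1.67 ± 0.07 and 1.29 ± 0.08, and the growth cone protein DPYSL3 by 1.31 ± 0.06. Of 23 neural stem and progenitor genes, 12 fell, 5 rose and 6 did not pass (12 and 5 adjusted over the list alone; adjusted p = 0.00652, and adjusted p = 0.156 with an estimated correlation). PAX6 led them, followed by TTYH1 (-1.31 ± 0.13), the receptor phosphatase PTPRZ1 (-1.21 ± 0.07) and the Hedgehog pathway repressor GLI3 (-1.18 ± 0.07). NES, the intermediate filament used as a stem cell marker, fell by 0.44 ± 0.11, and the pluripotency and progenitor factor SOX2 differed by -0.12 ± 0.11 (adjusted p = 0.441). The NES call ended without mutant array 2 (adjusted p = 0.0532).

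Some of the stress and metabolic lists also rose, by camera at the preset correlation. In the p53 and senescence list 11 of 24 genes rose, 2 fell and 11 did not pass (14 and 2 adjusted over the list alone; adjusted p = 9.47e-05, and adjusted p = 0.156 with an estimated correlation). IGFBP3 led them, with the cell cycle inhibitor CDKN1A (1.19 ± 0.08) and the death receptor FAS (1.11 ± 0.06), while the inhibitor CDKN1C fell (-1.18 ± 0.10). In the unfolded protein response 14 of 29 genes rose, 0 fell and 15 did not pass (14 and 0 adjusted over the list alone; adjusted p = 5.63e-06, and adjusted p = 0.17 with an estimated correlation). Among them were the lipoprotein receptor VLDLR (0.82 ± 0.07), the pseudokinase TRIB3 (0.73 ± 0.10) and the chaperone cofactor SDF2L1 (0.69 ± 0.08). For cholesterol synthesis the counts were 12 up, 0 down and 9 not passing of 21 (12 and 0 adjusted over the list alone; adjusted p = 4.92e-05, and adjusted p = 0.0551 with an estimated correlation). The mevalonate enzyme MVD rose by 0.58 ± 0.10 and ACAT2 by 0.40 ± 0.09. NRF2 targets rose in 13 of 28 cases, fell in 2 and did not pass in 13 (15 and 2 adjusted over the list alone; adjusted p = 0.00398, and adjusted p = 0.332 with an estimated correlation). The NADPH-producing ME1 rose by 1.52 ± 0.11 and the haem-degrading HMOX1 by 0.94 ± 0.08. Genes of the proteasome list rose in 10 of 30 cases, with 0 down and 20 not passing (10 and 0 adjusted over the list alone). Camera gave an adjusted p of 0.00256, and 0.5 with an estimated correlation. PSMD5 rose by 0.75 ± 0.07 and PSME3 by 0.56 ± 0.09.

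Of 44 DNA replication genes, 10 rose, 0 fell and 34 did not pass (11 and 0 adjusted over the list alone; adjusted p = 0.00648, and adjusted p = 0.36 with an estimated correlation), with the replisome gene CDC45 at 0.43 ± 0.07. Of 38 mitosis genes 6 rose and 32 did not pass (4 adjusted over the list alone; adjusted p = 0.0469, and adjusted p = 0.36 with an estimated correlation), with the kinesin KIF20A at 0.42 ± 0.06. The proliferation marker MKI67 differed by 0.23 ± 0.09 (adjusted p = 0.101, and 0.0177 without mutant array 1). ERK feedback genes rose in 12 of 27 cases, fell in 5 and did not pass in 10 (12 and 6 adjusted over the list alone; adjusted p = 0.0469, and adjusted p = 0.17 with an estimated correlation). The receptor signalling inhibitor SPRY1 rose by 1.94 ± 0.11 and the phosphatase DUSP4 by 1.22 ± 0.08, and the immediate early gene EGR3 fell by 1.26 ± 0.07. Interferon response genes rose in 13 of 34 cases, fell in 3 and did not pass in 18 (14 and 5 adjusted over the list alone; adjusted p = 0.0476, and adjusted p = 0.36 with an estimated correlation). The ubiquitin-like ISG15 rose by 1.32 ± 0.09 and the membrane protein IFITM1 fell (-1.03 ± 0.11). The last 3 calls lay near the threshold. ERK feedback passed no longer without wildtype array 1 (adjusted p = 0.058), wildtype array 2 (0.0662), mutant array 1 (0.0818) or treated array 3 (0.0571). The interferon call ended without wildtype array 2 (0.0662), wildtype array 3 (0.0705), mutant array 1 (0.0913) or treated array 3 (0.0571), and the mitosis call without wildtype array 2 (0.111), mutant array 2 (0.0576) or mutant array 3 (0.0784). With dim genes left out none of the 3 passed (ERK feedback 0.079, interferon 0.0535, mitosis 0.0535). ERK feedback was also lost with array weights (0.0604), interferon with another variance model (0.0527), and mitosis with a repeated quantile normalisation (0.0517) or centring (0.0507).

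The other 15 lists were not called by camera between mutant and wildtype cells, which does not show that they stayed unchanged. Of all 29 lists, fry, which tests against no change, called 22. Among 38 nuclear envelope genes, 7 rose, 7 fell and 24 did not pass (8 and 7 adjusted over the list alone; adjusted p = 0.952). LMNA, which encodes the A-type lamins, rose by 0.47 ± 0.12, and the nesprin gene SYNE1 by 0.85 ± 0.07. The LMNA call ended without wildtype array 1 or without mutant array 3 (adjusted p = 0.0539 each). The B-type lamins LMNB1 and LMNB2 differed by 0.02 ± 0.07 (adjusted p = 0.904) and 0.23 ± 0.10 (adjusted p = 0.142). Regional markers gave 0 up and 3 down of 13 for the forebrain (0 and 3 adjusted over the list alone; adjusted p = 0.093), with FEZF2 at -0.43 ± 0.09. The midbrain and hindbrain list had 1 up and 3 down of 13 (2 and 3 adjusted over the list alone; adjusted p = 0.367), with IRX5 at -1.98 ± 0.09 and GBX2 at -0.94 ± 0.12. HOX genes had 0 up and 3 down of 18 (0 and 2 adjusted over the list alone; adjusted p = 0.298), with HOXA2 at -0.82 ± 0.06. Glial lists gave 4 up and 4 down of 15 astrocyte genes (4 and 6 adjusted over the list alone; adjusted p = 0.952). The oligodendrocyte lineage had 3 up and 0 down of 12 genes (3 and 0 adjusted over the list alone; adjusted p = 0.054), where NKX2-2 was joined by MBP at 1.01 ± 0.13. The oligodendrocyte list passed without wildtype array 1 (adjusted p = 0.0312) or mutant array 3 (0.0218), the glycolysis and hypoxia list without wildtype array 1 (0.0366) or mutant array 2 (0.0378), and the forebrain list without mutant array 2 (0.043). With another variance model the oligodendrocyte and glycolysis lists (0.0497 each) and ribosomal proteins (0.0269) passed. The oligodendrocyte list also passed with a repeated quantile normalisation (0.0454) and array weights (0.0299), and the glycolysis list with the mean of all probe sets (0.0464).

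Remaining counts were 8 up and 12 down of 37 axon and synapse genes (8 and 13 adjusted over the list alone; adjusted p = 0.415), with the adhesion gene CNTNAP2 at -1.81 ± 0.09 and the guidance cue SEMA3C at 1.42 ± 0.07. WNT targets had 3 up and 4 down of 12 (3 and 4 adjusted over the list alone; adjusted p = 0.952). Pluripotency genes had 3 up and 3 down of 14 (3 and 3 adjusted over the list alone; adjusted p = 0.952), with DPPA4 at 1.54 ± 0.09. Glycolysis and hypoxia genes rose in 11 and fell in 4 of 32 cases (12 and 4 adjusted over the list alone; adjusted p = 0.0549), with the vasodilator peptide gene ADM at 2.13 ± 0.07 and the collagen cross-linking LOX at 1.85 ± 0.11. Heat shock genes had 2 up and 2 down of 17 (2 and 2 adjusted over the list alone; adjusted p = 0.415), with the small chaperone HSPB8 at 1.71 ± 0.09. Oxidative phosphorylation had 3 up and 2 down of 49 (2 and 0 adjusted over the list alone; adjusted p = 0.952). Ribosomal proteins had 0 up and 3 down of 37 (0 and 1 adjusted over the list alone; adjusted p = 0.101), with RPL31 at -0.54 ± 0.08. Lysosome and autophagy genes had 6 up and 4 down of 44 (6 and 4 adjusted over the list alone; adjusted p = 0.456). The median, mean and test statistic differed in sign for the pluripotency list (median -0.033, mean 0.099) and for WNT targets (median 0.003, mean -0.078).

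Among 17 measured familial Parkinson's disease genes, 1 rose, 3 fell and 13 did not pass in mutant cells (1 and 3 adjusted over the list alone; adjusted p = 0.493). RAB29, a small GTPase upstream of LRRK2, rose by 0.74 ± 0.06. MAPT, which encodes tau, fell by 1.10 ± 0.13, the phosphoinositide phosphatase SYNJ1 by 0.43 ± 0.07 and the clathrin uncoating cofactor DNAJC6 by 0.37 ± 0.08. The other 13 were PINK1, PARK7, UCHL1, ATP13A2, VPS35, FBXO7, GIGYF2, HTRA2, PLA2G6, EIF4G1, GAK, RAB8A and LRRK1, with changes between -0.36 (PLA2G6, adjusted p = 0.0664) and 0.34 (EIF4G1, adjusted p = 0.0971). PLA2G6 passed without wildtype array 2 (adjusted p = 0.0403) or mutant array 1 (0.0234), EIF4G1 without treated array 3 (0.048) and HTRA2 without mutant array 3 (0.032).

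**Figure D2:**
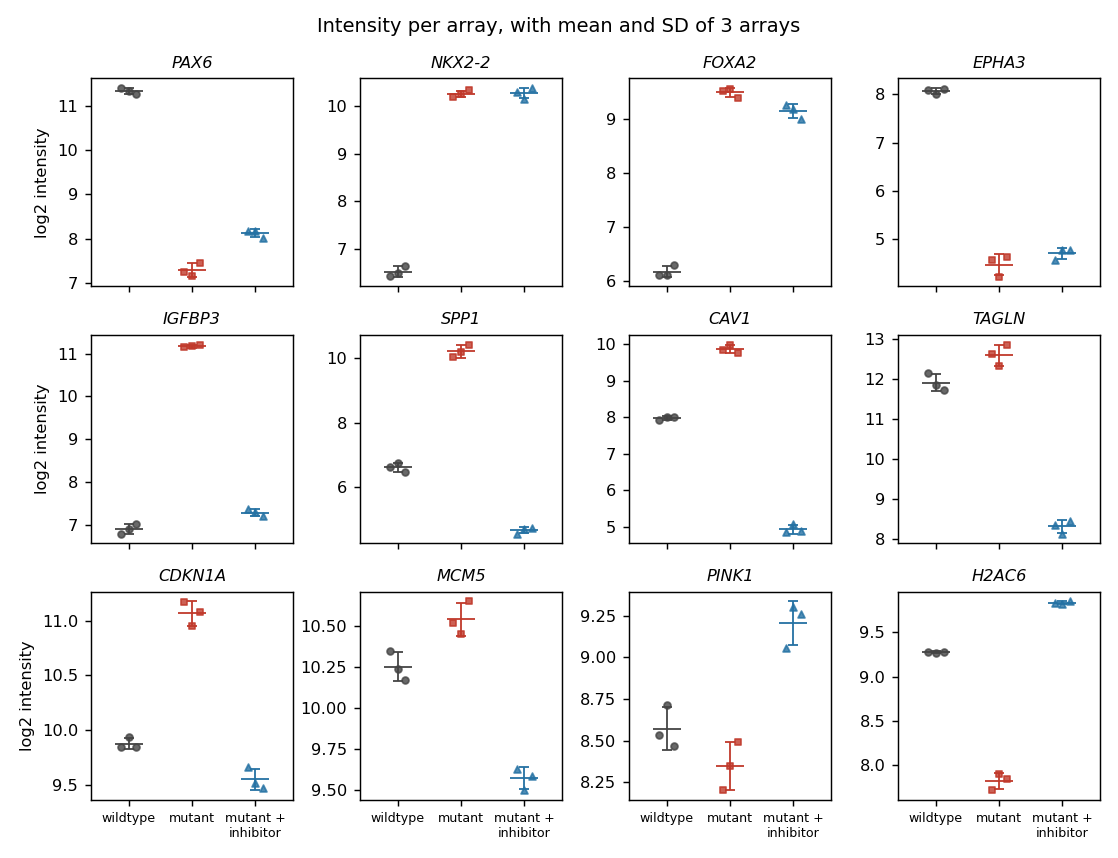
Log2 intensity on each of the 9 arrays (points, vertical axis) for 12 genes in wildtype, mutant and inhibitor-treated mutant cells (horizontal axis), with the mean and SD of 3 arrays as a line and bar. PAX6, NKX2-2, FOXA2 and EPHA3 stay off the wildtype level after treatment, IGFBP3 comes close to it, and SPP1, CAV1, TAGLN, CDKN1A and MCM5 fall below it.

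The largest single changes with LRRK2-IN-1 in mutant cells were decreases, among them contractile, matrix and membrane genes. SPP1 was 45.6-fold lower in treated than in mutant cells (log2 change -5.51 ± 0.11 SE, n = 3 per group), the muscle ankyrin repeat gene ANKRD1 33.9-fold lower (-5.08 ± 0.12) and CAV1, the coat protein of caveolae, 30.7-fold lower (-4.94 ± 0.08). The actin-binding TAGLN fell by 4.29 ± 0.15, the myosin light chain gene MYL9 by 4.16 ± 0.24 and the smooth muscle actin ACTG2 by 4.15 ± 0.08. Further decreases were in RGS5, a pericyte-enriched regulator of G protein signalling (-4.39 ± 0.09), the retinoic acid hydroxylase CYP26A1 (-4.32 ± 0.14), EMP1 (-4.22 ± 0.10) and GLIPR1 (-4.04 ± 0.09). The largest increase was 6.58-fold, in the metalloprotease gene TLL2 (2.72 ± 0.07).

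Other genes among the 10 largest increases were the T-type calcium channel gene CACNA1G (2.16 ± 0.09), the histone genes H2AC6 (2.02 ± 0.06) and H2BC5 (1.95 ± 0.07), and TXNIP, an inhibitor of thioredoxin and glucose uptake (2.00 ± 0.07). The list also held the brain cholesterol hydroxylase CYP46A1 (1.97 ± 0.08), the granzyme inhibitor SERPINB9 (1.93 ± 0.14), the guanine nucleotide exchange factor RALGPS1 (1.88 ± 0.06), the phospholipid flippase ATP8A1 (1.86 ± 0.09) and CDKN1C (1.86 ± 0.10). In total 4494 genes changed, 2411 up and 2083 down, and 539 of them at least 2-fold, 131 up and 408 down. The arrays of the groups did not overlap for 45.8% of genes, against 10% by chance. Of the 4494 genes, 4484 moved the same way in all 3 numbered pairs. For 4387 of the 4494 the arrays did not overlap, which fixes that outcome, so the count is no further support.

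Cell cycle genes fell. Of 44 DNA replication genes, 29 fell, 1 rose and 14 did not pass (31 and 1 adjusted over the list alone; adjusted p = 3.17e-09, and adjusted p = 0.208 with an estimated correlation). The polymerase subunit POLE2 fell by 1.09 ± 0.06, the helicase subunit MCM5 by 0.97 ± 0.08 and the clamp loader RFC3 by 0.74 ± 0.06. Of 38 mitosis genes, 16 fell, 0 rose and 22 did not pass (18 down and 1 up adjusted over the list alone; adjusted p = 0.00046, and adjusted p = 0.208 with an estimated correlation). PRC1 fell by 0.49 ± 0.06, the factor FOXM1 by 0.48 ± 0.08 and MKI67 by 0.48 ± 0.09. In the p53 and senescence list 8 of 24 genes fell, 3 rose and 13 did not pass (8 and 4 adjusted over the list alone; adjusted p = 0.0417, and adjusted p = 0.279 with an estimated correlation). Decreases were seen in IGFBP3 (-3.90 ± 0.08), FAS (-2.41 ± 0.06) and CDKN1A (-1.52 ± 0.08). The p53 call ended without mutant array 2 (adjusted p = 0.0664), mutant array 3 (0.0621) or treated array 1 (0.0584), and with dim genes left out (0.109).

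Matrix and mesenchyme genes had the lowest mean changes of the 29 fixed lists. Of 41 extracellular matrix genes, 26 fell, 5 rose and 10 did not pass (28 and 5 adjusted over the list alone; adjusted p = 1.27e-08, and adjusted p = 0.0787 with an estimated correlation). They included the adhesion-modulating TNC (-3.12 ± 0.09), the fibrillar collagen COL11A1 (-2.37 ± 0.10) and SERPINF1 (-2.34 ± 0.11). Of 24 neural crest and mesenchyme markers, 15 fell, 2 rose and 7 did not pass (16 and 2 adjusted over the list alone; adjusted p = 3.44e-06, and adjusted p = 0.208 with an estimated correlation). LUM fell by 3.83 ± 0.09, S100A4 by 2.33 ± 0.09 and the smooth muscle actin ACTA2 by 1.90 ± 0.06.

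Stress lists that were up in mutant cells were down with the inhibitor. NRF2 targets fell in 17 of 28 cases, rose in 3 and did not pass in 8 (17 and 3 adjusted over the list alone; adjusted p = 0.000216, and adjusted p = 0.208 with an estimated correlation). The quinone reductase NQO1 fell by 3.29 ± 0.07, ME1 by 2.31 ± 0.11 and the cystine transporter SLC7A11 by 1.37 ± 0.09. Unfolded protein response genes fell in 15 of 29 cases, rose in 2 and did not pass in 12 (15 and 2 adjusted over the list alone; adjusted p = 0.000242, and adjusted p = 0.208 with an estimated correlation). TRIB3 fell by 1.55 ± 0.10, the factor ATF3 by 1.19 ± 0.08 and PHGDH, the first enzyme of serine synthesis, by 1.15 ± 0.10. Interferon response genes fell in 16 of 34 cases, rose in 4 and did not pass in 14 (16 and 4 adjusted over the list alone; adjusted p = 0.00274, and adjusted p = 0.208 with an estimated correlation). Both ISG15 (-2.07 ± 0.09) and IFIT1 (-1.79 ± 0.09) fell. For cholesterol synthesis 11 of 21 fell, 1 rose and 9 did not pass (11 and 1 adjusted over the list alone; adjusted p = 0.00261, and adjusted p = 0.208 with an estimated correlation). FDPS (-0.69 ± 0.07) and NSDHL (-0.66 ± 0.09) fell most. Genes of the proteasome list fell in 13 of 30 cases, rose in 2 and did not pass in 15 (14 and 2 adjusted over the list alone). Camera gave an adjusted p of 0.00831, and 0.555 with an estimated correlation. PSMB6 was at -0.56 ± 0.09. Without mutant array 3 the proteasome list had an adjusted p of 0.0562.

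The remaining 19 lists were not called by camera for the inhibitor, which does not show that they stayed unchanged. Of all 29 lists, fry, which tests against no change, called 25. Neural stem and progenitor genes rose in 12 of 23 cases and fell in 5 (12 and 5 adjusted over the list alone; adjusted p = 0.103). TTYH1 rose by 1.49 ± 0.13, the glial and progenitor factor SOX9 by 1.00 ± 0.10, PAX6 by 0.83 ± 0.09, SOX2 by 0.47 ± 0.11 and NES by 0.44 ± 0.11. Neuronal differentiation genes rose in 13 and fell in 7 of 32 cases (16 and 7 adjusted over the list alone; adjusted p = 0.0847). The adhesion molecule NCAM1 rose by 1.27 ± 0.07, while the RNA-binding ELAVL4 fell by 1.45 ± 0.10 and the growth cone gene GAP43 by 1.23 ± 0.09. ERK feedback genes rose in 9 and fell in 11 of 27 cases (9 and 11 adjusted over the list alone; adjusted p = 0.0988). The ephrin receptor EPHA2 fell by 2.14 ± 0.08, the ETS factor ETV1 by 1.67 ± 0.10, DUSP4 by 1.60 ± 0.08 and SPRY1 by 1.52 ± 0.11. With dim genes left out the ERK list passed (0.0443), and with another variance model ribosomal proteins did (0.0307). Nuclear envelope genes rose in 8 and fell in 14 of 38 cases (8 and 16 adjusted over the list alone; adjusted p = 0.328). SYNE1 fell by 0.97 ± 0.07, the lamina-associated TMPO by 0.77 ± 0.07, LMNA by 0.35 ± 0.12 and LMNB2 by 0.29 ± 0.10. LMNB1 differed by -0.19 ± 0.07 (adjusted p = 0.0528) and passed without wildtype array 3 (0.0382) and with the replicate block (0.0434). The LMNA call ended without wildtype array 3, mutant array 2, mutant array 3, treated array 1 or treated array 2 (adjusted p from 0.0553 to 0.142). The LMNB2 call ended without any 1 array except mutant array 1 and treated array 3 (from 0.0578 to 0.161).

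Familial Parkinson's disease genes rose in 9 of 17 cases and fell in 1 (9 and 3 adjusted over the list alone; adjusted p = 0.0847). SYNJ1 rose by 1.02 ± 0.07, DNAJC6 by 1.00 ± 0.08, the mitochondrial kinase PINK1 by 0.86 ± 0.10, MAPT by 0.76 ± 0.13, and the mitochondrial protease HTRA2 by 0.72 ± 0.10. Smaller increases were in GIGYF2, by 0.43 ± 0.07, the lysosomal ATPase ATP13A2 by 0.38 ± 0.13, the kinase GAK by 0.33 ± 0.08 and the retromer subunit VPS35 by 0.20 ± 0.06, and RAB29 fell by 0.60 ± 0.06. The 7 genes PARK7, UCHL1, FBXO7, PLA2G6, EIF4G1, RAB8A and LRRK1 did not pass. The ATP13A2 call ended without wildtype array 2, mutant array 1, mutant array 2 or any treated array (adjusted p from 0.0538 to 0.13), and the VPS35 call without treated array 1 (0.0716) or treated array 2 (0.0511). Without treated array 3, EIF4G1 (0.0388), RAB8A (0.0415) and UCHL1 (0.0292) passed, and UCHL1 also passed without wildtype array 1 (0.048) or mutant array 2 (0.0256) and with the replicate block (0.047).

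Lysosome and autophagy genes rose in 18 and fell in 4 of 44 cases (19 and 4 adjusted over the list alone; adjusted p = 0.0747), with the autophagy kinase ULK1 up by 0.87 ± 0.09 and CLN3 down by 0.89 ± 0.08. This list passed with the replicate block on the 6 mutant and treated arrays (adjusted p = 0.0439), and without mutant array 3 (0.0425), treated array 1 (0.0469) or treated array 2 (0.0462). The endoderm and mesoderm list (adjusted p = 0.0747, 4 of 14 down) passed without treated array 1 (0.039).

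Treated mutant cells still differed from wildtype cells in 2943 genes, 1618 up and 1325 down, of which 231 changed at least 2-fold, 51 up and 180 down. NKX2-2 was 13.5-fold higher (log2 change 3.75 ± 0.08 SE, n = 3 per group), SELENOP 8.18-fold (3.03 ± 0.13) and FOXA2 7.8-fold (2.96 ± 0.09). CYP26A1 was 27.2-fold lower (-4.76 ± 0.14), COL1A2 18.8-fold (-4.24 ± 0.07), TFAP2B 18.7-fold (-4.22 ± 0.17) and PAX6 9.27-fold (-3.21 ± 0.09). The other large decreases were TAGLN (-3.60 ± 0.15), RGS5 (-3.42 ± 0.09), EPHA3 (-3.35 ± 0.11), the galectin LGALS1 (-3.32 ± 0.08), MYL9 (-3.29 ± 0.24) and the calcium pump regulator SLN (-3.21 ± 0.07). The other large increases were the glycosyltransferase GALNT3 (2.57 ± 0.07), CACNA1G (2.44 ± 0.09), the cadherins CDH6 (1.96 ± 0.08) and CDH7 (1.72 ± 0.23), the collagen-modifying PLOD2 (1.83 ± 0.07), ARAP2 (1.72 ± 0.15) and TLL2 (1.66 ± 0.07). The arrays of these groups did not overlap for 41.9% of genes, where chance gives 10%.

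DNA replication genes were below the wildtype level in 26 of 44 cases, above it in 0 and not passing in 18 (28 and 0 adjusted over the list alone; adjusted p = 5.94e-09, and adjusted p = 0.391 with an estimated correlation). POLE2 was at -0.70 ± 0.06, MCM5 at -0.68 ± 0.08 and the primase PRIM1 at -0.49 ± 0.09. For mitosis 5 of 38 genes fell, 1 rose and 32 did not pass (5 and 1 adjusted over the list alone; adjusted p = 0.0418, and adjusted p = 0.472 with an estimated correlation), with the cyclin CCNA2 at -0.47 ± 0.09. This call ended without wildtype array 3 (0.0612) or treated array 1 (0.073). MKI67 differed by -0.25 ± 0.09 (adjusted p = 0.0767, and 0.0325 without mutant array 1) and CDKN1A fell by 0.33 ± 0.08. Neuronal differentiation genes were lower in 16 of 32 cases, higher in 3 and not passing in 13 (17 and 3 adjusted over the list alone; adjusted p = 0.000463, and adjusted p = 0.0929 with an estimated correlation). ELAVL4 was at -1.63 ± 0.10, GAP43 at -1.48 ± 0.09 and STMN2 at -1.34 ± 0.07. Neural crest and mesenchyme markers were lower in 9 of 24 cases, higher in 3 and not passing in 12 (9 and 4 adjusted over the list alone; adjusted p = 0.00776, and adjusted p = 0.472 with an estimated correlation). NRF2 targets were lower in 9 of 28 cases, higher in 0 and not passing in 19 (9 and 0 adjusted over the list alone; adjusted p = 0.0217, and adjusted p = 0.472 with an estimated correlation), with NQO1 at -2.51 ± 0.07. The NRF2 call ended without treated array 1 (0.0537) and with dim genes left out (0.0785).

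Lists above the wildtype level were lysosome and autophagy genes and familial Parkinson's disease genes. Of 44 lysosome and autophagy genes, 16 rose, 2 fell and 26 did not pass (18 and 3 adjusted over the list alone; adjusted p = 0.00269, and adjusted p = 0.472 with an estimated correlation). The sialidase NEU1 rose by 0.85 ± 0.11, the membrane protein SCARB2 by 0.59 ± 0.10 and the cholesterol transporter NPC1 by 0.57 ± 0.08, and the thioesterase PPT1 fell by 0.74 ± 0.07. Of 17 familial Parkinson's disease genes, 6 rose, 0 fell and 11 did not pass (6 and 0 adjusted over the list alone; adjusted p = 0.0441, and adjusted p = 0.45 with an estimated correlation). They were PINK1 (0.63 ± 0.10), DNAJC6 (0.63 ± 0.08), SYNJ1 (0.59 ± 0.07), HTRA2 (0.53 ± 0.10), GIGYF2 (0.32 ± 0.07) and VPS35 (0.23 ± 0.06; adjusted p = 0.057 without treated array 1). This call lay near the threshold and ended without wildtype array 2 (adjusted p = 0.0665), wildtype array 3 (0.0612), mutant array 2 (0.0693) or treated array 1 (0.0516), after a repeated quantile normalisation (0.0633) and with dim genes left out (0.0914).

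The other 22 lists were not called by camera against wildtype, which does not show that they matched it. Of all 29 lists, fry called 20. Extracellular matrix genes rose in 11 and fell in 14 of 41 cases (12 and 15 adjusted over the list alone; adjusted p = 0.294), with COL11A1 at -2.79 ± 0.10, TNC at -2.34 ± 0.09 and SPP1 at -1.93 ± 0.11 below wildtype. Neural stem and progenitor genes rose in 7 and fell in 8 of 23 cases (7 and 8 adjusted over the list alone; adjusted p = 0.367), with GLI3 at -1.62 ± 0.07 and the Notch target HES1 at 1.32 ± 0.12. SOX2 rose by 0.35 ± 0.11, a call that ended without wildtype array 1, 2 or 3 or treated array 3 (adjusted p from 0.0627 to 0.0911), and NES differed by -0.01 ± 0.11 (adjusted p = 0.979). Nuclear envelope genes rose in 2 and fell in 4 of 38 cases (2 and 4 adjusted over the list alone; adjusted p = 0.327). LMNA, LMNB1 and LMNB2 differed by 0.12 ± 0.12, -0.17 ± 0.07 and -0.06 ± 0.10 (adjusted p = 0.516, 0.0957 and 0.714). The oxidative phosphorylation list had 1 up and 6 down of 49 (1 and 5 adjusted over the list alone; adjusted p = 0.072), and passed without treated array 3 (0.0106), with dim genes left out (0.0119), with the mean of all probe sets (0.034), with another variance model (0.0336) and with array weights (0.0267). Interferon response genes, with 3 up and 6 down of 34 (3 and 6 adjusted over the list alone; adjusted p = 0.0742), passed with dim genes left out (0.0421) and with the mean of all probe sets (0.034).

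**Figure D3:**
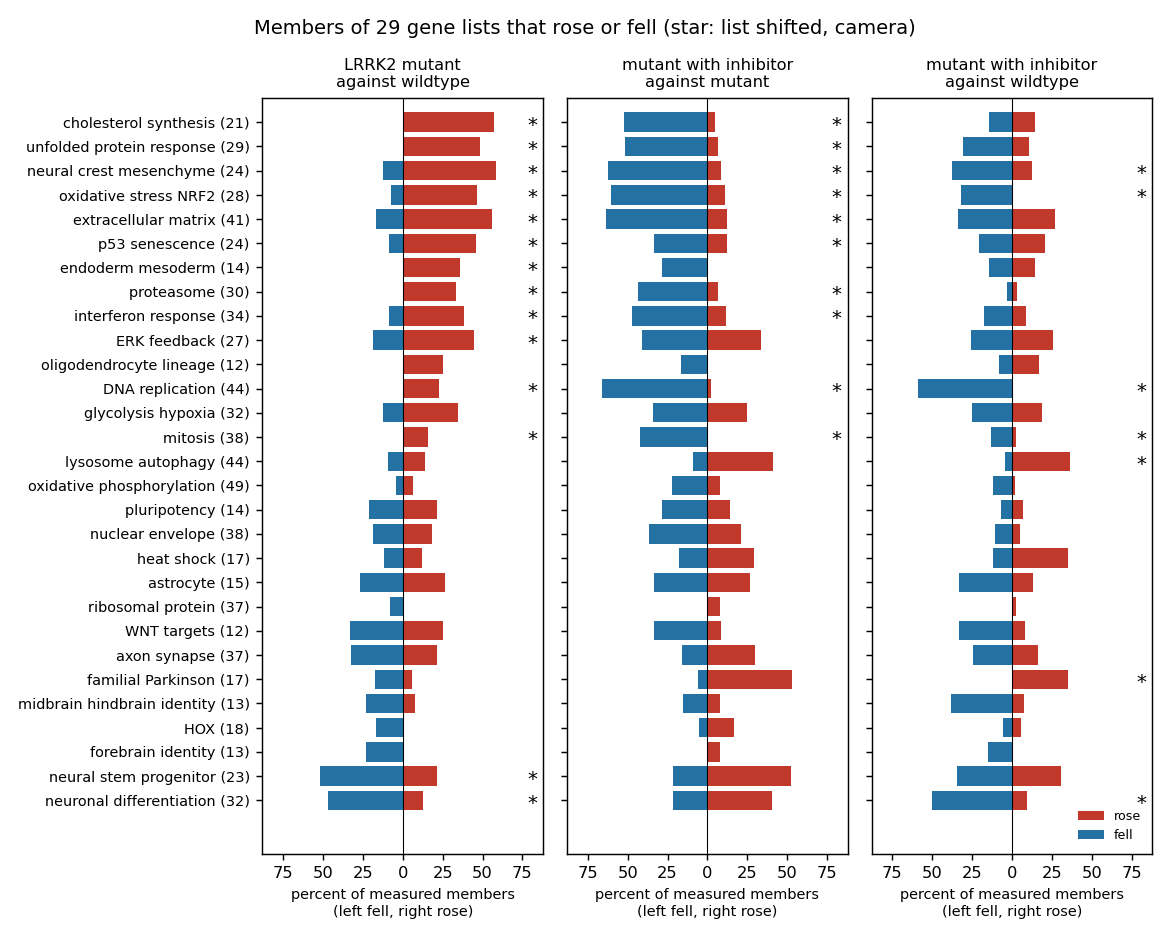
Percent of measured members of 29 gene lists that rose (right, red) or fell (left, blue) in each of the 3 comparisons, with the number of measured members in brackets and a star where the list was shifted by camera at the preset correlation. Shifted lists number 14 in mutant against wildtype cells, 10 in treated against mutant cells and 7 in treated against wildtype cells.

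Most genes changed in mutant cells moved back with the inhibitor. Of the 2832 genes changed in mutant cells, 2547 (89.94%) had an inhibitor change of the opposite sign. Both comparisons share the 3 mutant arrays, and simulated data with no inhibitor effect gave 59% on average and 60.8% at most. In the data 2064 of these genes passed the test in the opposite direction, 1140 of them up in mutant cells and 924 down, where independent calls would give 258.6 and 271.5. No simulated set gave more than 1, but without an inhibitor effect hardly any gene can pass its test, so that count was fixed by the setting. Another 122 changed further in the same direction and 646 did not change with the inhibitor. Across genes the changes correlated at r = -0.69, against -0.137 in simulated sets, and their covariance was -0.1252, against -0.00559 added by the shared arrays (genes are not independent replicates). With 3 mutant arrays the group could not be split so as to keep 2 arrays in each part, so part of the excess over independent calls may come from the shared arrays.

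Of the 2064 genes that changed back, 1168 did not differ from wildtype after treatment, 159 still differed in the mutant direction and 737 differed in the opposite direction, past the wildtype level. IGFBP3 fell back from 4.27 ± 0.08 to 0.38 above wildtype, while SPP1 went from 3.58 ± 0.11 above wildtype to 1.93 ± 0.11 below it. NKX2-2 did not move back with the inhibitor (0.01 ± 0.08), and EPHA3 changed by 0.23 ± 0.11 and PRDM13 by -0.11 ± 0.11. Both mutant groups differed from wildtype in the same direction for 632 genes, 328 up and 304 down, where independent calls would give 200.8 and 149.2, and 60 of them were at least 2-fold off wildtype in both groups, 17 higher and 43 lower. Simulated sets with no effect in any group gave at most 1 gene changed the same way in both. Without effects hardly any gene can pass, so this count does not show how much the shared wildtype arrays add. The changes of both mutant groups against wildtype correlated at r = 0.113 across genes, with a covariance of 0.0149 against 0.00559 from the shared arrays. Shared wildtype arrays give r = 0.5 where no group has an effect, so that value is no measure for data with effects. A further 2308 genes changed with the inhibitor and not detectably between mutant and wildtype cells.

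**Figure D4:**
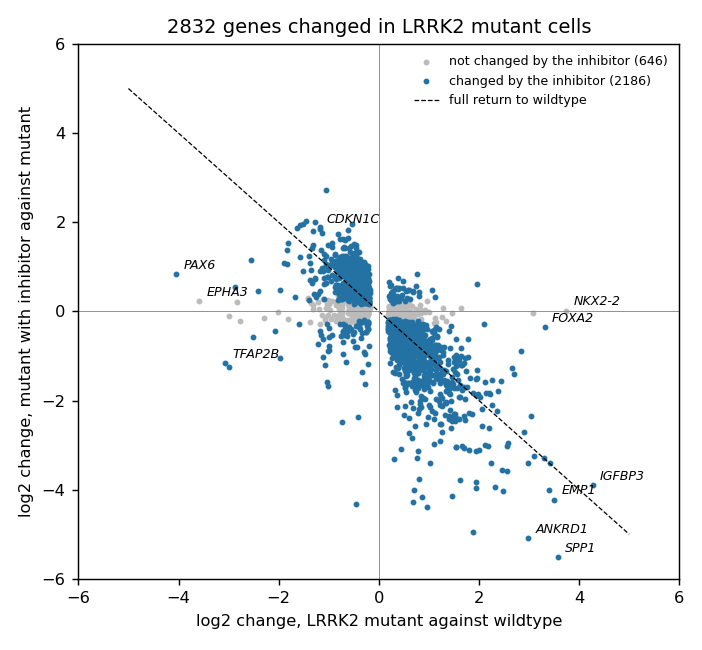
Log2 change with the inhibitor (vertical axis) against log2 change in mutant cells (horizontal axis) for the 2832 genes changed in mutant cells, blue where the inhibitor change passed the test and grey where it did not (646 genes). The dashed line marks a full return to the wildtype level, and NKX2-2, FOXA2, EPHA3 and PAX6 lie near the horizontal axis.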

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

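Probe sets that carry several gene symbols or none were left out of all gene results, 3151 in number. Tested in the same limma model, 427 of them (13.6%) changed between mutant and wildtype cells, 694 (22%) between treated and mutant cells and 413 (13.1%) between treated and wildtype cells, with 23, 73 and 26 changed at least 2-fold. No gene was assigned to them, and why the comparison of treated with mutant cells gave the largest share was not tested.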

How the results depend on the processing

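The number of changed genes was robust to scaling, but the majority direction in mutant against wildtype cells was not. Of these calls 52.4% were up in the main fit, 49.7% with a repeated quantile normalisation and 48.2% with each array centred. For mutant against wildtype cells 2832 genes became 3008 with a repeated quantile normalisation, 2137 with dim genes left out, 3057 with the replicate block, and between 2155 and 2864 with 1 array left out; a 2-fold threshold left 330. For treated against mutant cells 4494 became 4544, 3353, 4674 and 3785 to 4571, with 6804 when every probe set was tested and 539 at 2-fold. For treated against wildtype cells 2943 became 2958, 2357, 3232 and 2179 to 3052, with 3872 under array weights and 231 at 2-fold. The F test gave 7347 with every probe set, against 4883. Corrected distances fell to 0.322 (mutant to wildtype) with the mean of all probe sets of a gene and 0.3227 with every probe set, to 0.4363 and 0.4271 (treated to mutant), and to 0.3112 and 0.3069 (treated to wildtype). On the scale of 1 minus Pearson r they were 0.0106 (mutant to wildtype), 0.0175 (treated to mutant) and 0.00928 (treated to wildtype). The share moved back stayed between 88.91% and 91.18%. The lists depended on the test. Over the 29 lists, camera called 14 in mutant against wildtype cells, 9 with dim genes left out and 1 with an estimated correlation, and fry, which tests against no change, called 22. In treated against mutant cells camera called 10, or 0 with an estimated correlation, and fry called 25. In treated against wildtype cells the counts were 7, 0 and 20, and leaving out 1 array gave 4 (without treated array 1) to 8. The replicate block also pairs the wildtype arrays by number, which their correlations did not bear out. With it, interferon genes in mutant cells (adjusted p = 0.0572) and familial Parkinson's disease genes in treated against wildtype cells (0.0513) no longer passed. PLA2G6 (0.0229), EIF4G1 (0.0256), GAK (0.0399) and MKI67 (0.047) passed in mutant against wildtype cells, and MKI67 (0.0334) in treated against wildtype cells. Largest shifts of the all-gene median were 0.0202 and 0.0336. The cause was not tested.

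Where every probe set was tested separately, another probe set of some named genes had the opposite sign. In mutant against wildtype cells these were CDKN1C 0.037, DNAJC6 0.06, EPHA3 0.069, GABRA5 -0.019, LMNA -0.021, LOX -0.071, ME1 -0.077, PSMD5 -0.1, PSME3 -0.375 and SYNE1 -0.002. In treated against mutant cells they were ACTA2 0.06, CACNA1G -0.012, DNAJC6 -0.065, LMNA 0.006, ME1 0.058, MKI67 0.119, NCAM1 -0.024 and TMPO 0.035. In treated against wildtype cells they were CACNA1G -0.033, DNAJC6 -0.005, EPHA3 0.03, GALNT3 -0.234, HES1 -0.022, IGFBP3 -0.024 and TNC 0.094. Their adjusted p ranged from 0.117 to 0.988.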

Other observations

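All gene lists and gene choices in these paragraphs were made after the values were seen. List p-values here were adjusted over these 5 lists only, so they cannot be set beside those of the 29 fixed lists. Lists picked for their movement tend to pass, so the p-values describe the pattern and do not test it. Actin and SRF target genes, which respond to the state of the actin skeleton, rose in mutant cells in 16 of 18 cases with 0 down (16 and 0 adjusted over the list alone; camera adjusted p = 2.17e-13, and adjusted p = 0.0135 with an estimated correlation). With the inhibitor 17 fell and 0 rose (18 and 0 adjusted over the list alone; adjusted p = 4.43e-17, and 0.00883 with an estimated correlation). Against wildtype, 12 were lower in treated cells (14 adjusted over the list alone; adjusted p = 3.59e-12, and 0.0215 with an estimated correlation). The cardiac actin ACTC1 differed from wildtype by 2.32 in mutant and -1.62 in treated cells, and the calponin CNN1 by 1.54 and -1.51. YAP and TEAD targets gave 8 up and 1 down of 13 in mutant cells (adjusted p = 8.75e-06, and 0.0135 with an estimated correlation). With the inhibitor 9 fell and 0 rose (adjusted p = 1.23e-06, and 0.00918 with an estimated correlation), and against wildtype 2 were higher and 6 lower (adjusted p = 0.00656, and 0.0482 with an estimated correlation). ANKRD1 rose by 2.98 in mutant cells and the receptor kinase gene AXL by 1.81.

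Dorsal neural tube genes fell in mutant cells in 6 of 14 cases and rose in 3 (adjusted p = 0.00109, and 0.0479 with an estimated correlation). With the inhibitor 2 rose and 4 fell, and the list was not called (adjusted p = 0.361). In treated cells 7 of these genes were lower and 2 higher than in wildtype cells (adjusted p = 7.33e-05, and 0.0482 with an estimated correlation). Ventral neural tube genes rose in 5 of 11 cases and fell in 1 in mutant cells (adjusted p = 0.00213, and 0.0277 with an estimated correlation), and had 1 up and 3 down with the inhibitor (adjusted p = 0.332). Against wildtype, treated cells had the same 5 genes higher, FOXA1, FOXA2, NKX2-2, NKX6-1 and SHH, and a different gene lower (adjusted p = 0.011, and 0.0482 with an estimated correlation). Clustered histone genes fell in 10 of 42 cases in mutant cells and rose in 0 (adjusted p = 0.00389, and 0.0479 with an estimated correlation). They rose in 13 cases and fell in 2 with the inhibitor (adjusted p = 0.00197, and 0.0486 with an estimated correlation), and were higher in 8 and lower in 2 against wildtype (adjusted p = 0.0362, and 0.115 with an estimated correlation). H2AC6 fell by 1.46 in mutant cells and rose by 2.02 with the inhibitor.

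The tests of the patterns that follow were chosen only after the results were seen, except the test of intensity and the splits of arrays. Actin and SRF genes lay below wildtype in treated cells, with a median of -0.624. A loss of mesenchymal or neural crest cells stays open. The median of the other 22 markers of these cells was -0.0894 (95% bootstrap interval -0.314 to 0.104), but 7 of them were lower and 3 higher than in wildtype, and such a median decides nothing. The 180 genes nearest in intensity had a median of 0.0531 (-0.00645 to 0.114), which argues against a normalisation effect of intensity. Inhibition of a kinase other than the mutant one stays open for the 12 of 18 genes below wildtype, since no treated wildtype cells were among the 9 arrays.

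Of 15 dorsal and ventral neural tube genes changed in mutant cells, 13 differed from wildtype in the same direction after treatment, 6 of them at least 2-fold in both mutant groups. The median moved 20.2% of the way back (bootstrap interval -0.364 to 23.8), from -38.4% for ZIC1 and 0.368% for PAX3 to 40.4% for SHH, 61.3% for BMP7, 72.7% for PTCH1 and 125% for MSX1. These genes were chosen for this pattern, so their values leave open whether kinase activity was still needed at the time of treatment. Derivation of the line and genotype cannot be told apart for the 60 genes at least 2-fold off wildtype in both mutant groups, since no further knock-in line is labelled.

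Most mutant-changed genes moved back with the inhibitor. The share of 89.94% lies above the 60.8% reached at most by simulated sets with no inhibitor effect, which argues against the shared mutant arrays as the whole cause. A technical shift of the mutant arrays as the only difference would bring treated cells back to wildtype and not past it, but 737 genes went past it. Simulated sets gave at most 1 such gene, but they held equal treated and wildtype means, so that count was fixed by the setting. For the 737 genes a shift together with a separate effect of the inhibitor was not tested. For the 1168 genes that changed back and did not differ from wildtype a technical shift of the mutant arrays stays open, since the labels give no order of arrays. No biological explanation was tested.

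Splits of the same arrays were counted with limma. The 6 mutant and wildtype arrays can be parted into 3 and 3 in 10 ways, too few for a share below 0.05. The real split gave 2832 genes (1 of 10 as large) and the highest other 0, with up to 706 at an unadjusted p under 0.05 against 4190. It gave 14 lists (1 of 10) against at most 12. For treated and mutant arrays the values were 4494 genes (1 of 10) against 0, with up to 653 at an unadjusted p under 0.05 against 5273, and 10 lists against at most 10 (2 of 10). For treated and wildtype arrays they were 2943 genes (1 of 10) against 0, with up to 358 at an unadjusted p under 0.05 against 4325, and 7 lists (1 of 10) against at most 4. Of 100 drawn splits of the 9 arrays into 3 groups, from 280 possible, only the real one (1) reached 4883 genes in the F test, and the highest other gave 1543, which argues against a random division of the arrays as the source of the count.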
